A study of Mus musculus with 17 samples.

How the data were processed

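Messenger RNA of mouse inguinal white adipose tissue, a subcutaneous fat depot, was sequenced in 11 libraries. The labels place 4 in wild type, 4 in a homozygous knock-in of the p53 mutation R178C and 3 in a homozygous p53 knockout, all of strain C57BL/6. Total RNA was purified on columns and mRNA was isolated on beads, per the labels' protocols. A further 6 samples, 3 of p53 chromatin immunoprecipitation and their inputs from cultured adipocytes, were not analysed here. The labels do not say whether the libraries of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

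Each deposited file gave, for 29082 RefSeq transcripts, a read count per transcript, per the file headers. Beside it stood an RPKM value, which scales the count to transcript length and library total, also computed by the authors, per the file headers. The submitters' processing notes name bcl2fastq, Bowtie2, SICER 1.1 and the mouse genome build mm9 without a role for each. The counting tool, its treatment of reads shared between genes and its use of strand are not given in the sources used here. RPKM entered only a check of transcript length and library totals. Reads shared between near-identical genes, such as the beta-globin and Nlrp1 families, or between overlapping genes can have been assigned to either or counted for both, so values of these genes are uncertain.

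Transcript accessions were matched to gene symbols in a RefSeq table of assembly GRCm38.p6, which served only for names and gene order because its build differs from that of the files. The match gave a symbol for 28432 transcripts, and the other 650, with 0.920% to 1.16% of the counts of a library, were left out. A gene with several transcripts (3760 of 22459 genes) was represented by its most counted one over all libraries, because transcripts of a gene can share reads. That was not the longest transcript for 756 genes. The totals were 13895915 to 22565588 counts over all transcripts and 10100432 to 16366222 with 1 transcript per gene.

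Differential expression was tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr, which left 14127 genes, and the quasi-likelihood F test on all 3 groups in one fit, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of F. Levels are counts divided by the TMM-scaled library total (CPM), as mean ± SD over libraries, and means over a list are of log2 CPM with a prior count of 2. Gene lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the 26 lists with at least 5 genes tested. Camera with the correlation estimated from the data and fry, also of limma, were the alternatives, the latter asking whether the genes of a list move one way on balance without comparing them with other genes. The design, the gene lists and most of the alternatives were fixed before the data were examined.

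The 14 pathway lists covered p53 target genes, lipolysis and beta-adrenergic signalling, fatty acid oxidation, fatty acid and triglyceride synthesis, brown and beige adipocyte genes, oxidative phosphorylation, mitochondrial biogenesis and the tricarboxylic acid cycle, cholesterol synthesis, cell cycle, circadian clock, immediate early and stress genes, interferon response, adipose inflammation and extracellular matrix. The 14 cell type lists held markers of adipocytes, stromal cells, macrophages, B cells, T cells, neutrophils, erythrocytes, endothelium, smooth muscle, skeletal muscle, mammary epithelium, skin and nerve, and sex-linked genes. A value was found for 651 of their 657 entries. The neutrophil list, with 4 genes tested, and the sex-linked list were not tested. Some genes stand in more than 1 list, and the fat tissue itself expresses members of several of the marker lists at a low level.

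Genes were named by a fixed rule: per comparison the 10 largest log2 fold changes in each direction among genes past the threshold whose groups did not overlap, of each list up to 4 members with the smallest p (2 where none passed), and Trp53, Cdkn1a, Mdm2, Adrb3, Pnpla2, Lipe, Ucp1, Ppargc1a, Lep and Adipoq. Genes with only a clone number as name are given as a count or by that name. Genes named outside the rule are said to be so.

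The alternatives were each library left out in turn, only the 2 groups compared in the fit, the replicate number as a block, no filter on low counts, a mean count of at least 50, DESeq2's size factors, the Wald test of DESeq2 1.42.0, voom with library weights, and the mean of the B cell or of the mammary epithelium markers as a covariate. Libraries of wild type and R178C with the same number deviated together from their group means (correlations of 0.625, 0.261, 0.223 and 0.117, each above 0.1; median of pairs with other numbers −0.0923, over all groups), so their numbers were taken as pairs, from the data and not from the labels. This was decided after the calls with the block had been seen. The pair of number 4 was weak, as wild-type library 4 correlated more with R178C libraries 2 (0.133) and 3 (0.131). Deviations from a group mean add up to 0 within the group, which pushes pairs with other numbers below 0. Their median is therefore no neutral reference. Chosen after the data had been seen were the longest transcript per gene, the unmatched transcripts kept, and the first library of each group left out. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 prepared the tables, the permutation tests and the plots.

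The pipeline was tested on simulated counts with the means and library sizes of the real libraries. For R178C against wild type (14033 genes) the share of changed genes called was 12.1% at a log2 fold change of 0.5, 74.6% at 1 and 98.5% at 2. For the knockout against wild type (14030 genes) it was 9.09%, 91.0% and 97.0%, and for R178C against the knockout (14052 genes) 15.2%, 68.7% and 95.5%. Each share is over only the 66 or 67 genes given a change of that size. It was not determined separately for genes with few counts, so it need not hold for all genes tested. The calls among unchanged genes numbered 8 of 13803, 7 of 13800 and 4 of 13822.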

Results

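Inguinal white adipose tissue, the subcutaneous fat pad of the mouse groin, was profiled by RNA sequencing in mice of 3 p53 genotypes. Of the 11 libraries, 4 were wild type, 4 carried the p53 mutation R178C on both alleles and 3 lacked p53. R178C is an arginine-to-cysteine change in the DNA-binding part of the protein, made as the mouse counterpart of a human germline mutation. The libraries held 13895915 to 22565588 counts over all transcripts and 16242 to 16960 detected genes, and 14127 genes were tested. The Y-linked gene Ddx3y had 691 to 1371 counts and Xist 0 to 18 in all 11 libraries.

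To check the genotypes, Trp53, the gene encoding p53, was examined first. Its level was 28.8 ± 4.20 CPM in wild type (SD, n = 4), 28.9 ± 3.52 CPM in R178C (n = 4) and 14.2 ± 5.97 CPM in the knockout (n = 3). The knockout libraries had 20.4, 8.54 and 13.6 CPM (322, 133 and 161 counts), and the lowest of the other libraries had 25.8 CPM. Counts cover the whole transcript and the deleted part is not given in the labels. The antisense gene Wrap53 overlaps Trp53 and the use of strand is not stated, so the remaining counts were no measure of intact transcript. The log2 fold change of Trp53 in the knockout was −1.02 ± 0.244 (SE; edgeR adjusted p = 0.175), and without knockout library 1 it was −1.40 ± 0.194 (adjusted p = 0.0111). Over all alternatives the adjusted p ran from 0.000105 to 0.553. In R178C the log2 fold change of Trp53 against wild type was 0.00 ± 0.218 (adjusted p = 0.998).

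Knockout library 1 stood apart from the other 10. Its B cell markers had a mean of 6.64 log2 CPM, against 0.19 and 4.49 in the other two knockout libraries, 3.98 to 5.41 in wild type and 2.73 to 5.09 in R178C. Its T cell markers had a mean of 6.31, against 0.82 to 3.90 in the other 10, and its cell cycle genes 3.35, against 1.18 to 1.86. Its macrophage markers were at 5.82, but knockout libraries 2 and 3, at 5.31 and 5.64, were also above the 5.17 to 5.21 of wild type. Adipocyte markers were lower in it, at 9.92 log2 CPM against 10.6 to 10.8 in wild type and 10.8 and 10.7 in the other two knockout libraries. The 20 most counted genes took 13.6% of its counts and 20.2% to 23.2% in the others, and it set the first principal component, with 60.7% of the variance. The chi-square per degree of freedom between library pairs of the same group was 155.7 and 95.5 for the pairs with this library and 2.55 to 13.7 for all other pairs, so no pair agreed within sampling noise. The 4 neutrophil genes had a mean of 1.68 to 2.48 log2 CPM in wild type, 1.28 to 2.38 in R178C and 1.29 to 2.23 in the knockout.

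**Figure D1:**
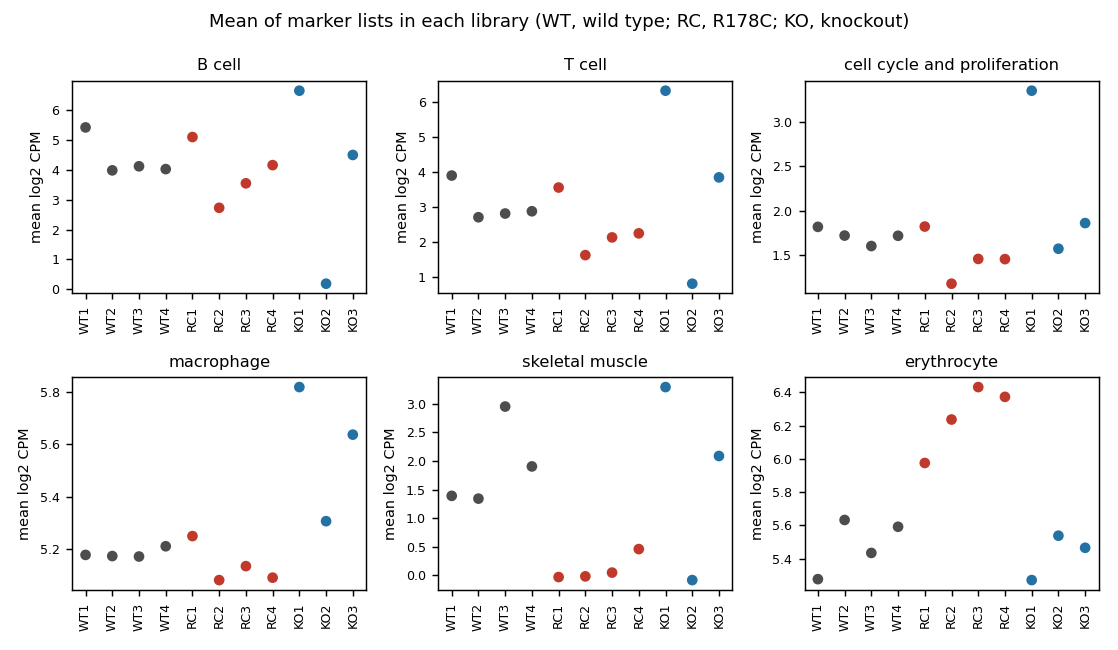
Mean log2 CPM of 6 marker lists in each of the 11 libraries, with the points coloured by genotype. Knockout library 1 was the highest for B cell (6.64), T cell (6.31), cell cycle (3.35) and macrophage (5.82) genes and knockout library 2 the lowest for B cells (0.19), and the R178C libraries had erythrocyte means of 5.98 to 6.43 against 5.28 to 5.63 in wild type.

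To ask what the R178C mutation changed in fat, the 4 R178C libraries were compared with wild type. Of 14127 genes, 2 rose and 6 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). C2cd2l, which encodes a lipid transfer protein at contacts between endoplasmic reticulum and plasma membrane, rose from 50.6 ± 2.0 to 106 ± 23.4 CPM (SD, n = 4 each). Its log2 fold change was 1.06 ± 0.134 (SE, adjusted p = 0.0193). St3gal4, a sialyltransferase gene, rose from 25.5 ± 1.18 to 35.8 ± 1.46 CPM. Slc7a11, the cystine transporter gene known as a target of p53 repression, fell from 39.3 ± 3.14 to 22.5 ± 1.43 CPM (log2 −0.80 ± 0.082, adjusted p = 0.0138). Spsb1, an adaptor of a ubiquitin ligase, fell from 53.9 ± 7.35 to 28.6 ± 1.48 CPM (−0.91 ± 0.103, adjusted p = 0.0138). Zmiz1, a transcriptional coregulator, fell from 222 ± 14.1 to 146 ± 5.96 CPM (−0.60 ± 0.068, adjusted p = 0.0138). The receptor-type phosphatase genes Ptprf (−0.86) and Ptpre (−0.77) and the zinc finger gene Hivep2 (−0.54) fell as well, at adjusted p = 0.0193, 0.0459 and 0.0193. With the replicate number as a block 14 genes passed, 6 of the 8 among them, and St3gal4 (adjusted p = 0.0824, against 0.0459) and Ptpre (0.0740) were not called.

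Among the genes of lipid breakdown, none passed the test. The beta-3 adrenergic receptor gene Adrb3 had 1196 ± 107 CPM in wild type and 1676 ± 139 CPM in R178C (log2 0.49 ± 0.194, adjusted p = 0.489). The triglyceride lipase gene Pnpla2 had a log2 fold change of 0.30 (adjusted p = 0.625) and the hormone-sensitive lipase gene Lipe one of 0.15 (0.884). Leptin, Lep, had 617 ± 99.0 CPM in wild type and 309 ± 44.9 CPM in R178C (−0.995 ± 0.223, adjusted p = 0.167), and the adipokine gene Adipoq a log2 fold change of 0.26 (0.775). The thermogenic genes Ucp1 (−0.55, adjusted p = 0.595) and Ppargc1a (−0.45, 0.595) did not pass, nor did the p53 target genes Cdkn1a (−0.35, 0.464) and Mdm2 (−0.15, 0.780).

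The count of genes moved with the libraries in the fit. With only wild type and R178C in the fit, 389 genes passed (176 up, 213 down), and without knockout library 1 it was 423 (191 up, 232 down), both sets holding all 8 genes. In the fit of the 2 groups Lep fell (adjusted p = 0.00654) and Adrb3 rose (adjusted p = 0.0211). There 4 members of the lipolysis list, 3 of fatty acid oxidation, 3 of synthesis and 7 of the erythrocyte list passed upward over all genes, and 7 of the skeletal muscle list downward. Over all alternatives the adjusted p ran from 0.00247 to 0.496 for Lep and from 0.0164 to 0.864 for Adrb3. The count was 0 without wild-type library 2 or without R178C library 4 (edgeR, with 1052 and 977 genes at an unadjusted p under the threshold). It was 1 without R178C library 3 and 2 without wild-type library 3 or R178C library 2. The count was 4 without wild-type library 1 or 4, R178C library 1 or knockout library 3. DESeq2's Wald test called 143 genes and voom with library weights 552 on all 11 libraries.

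**Figure D2:**
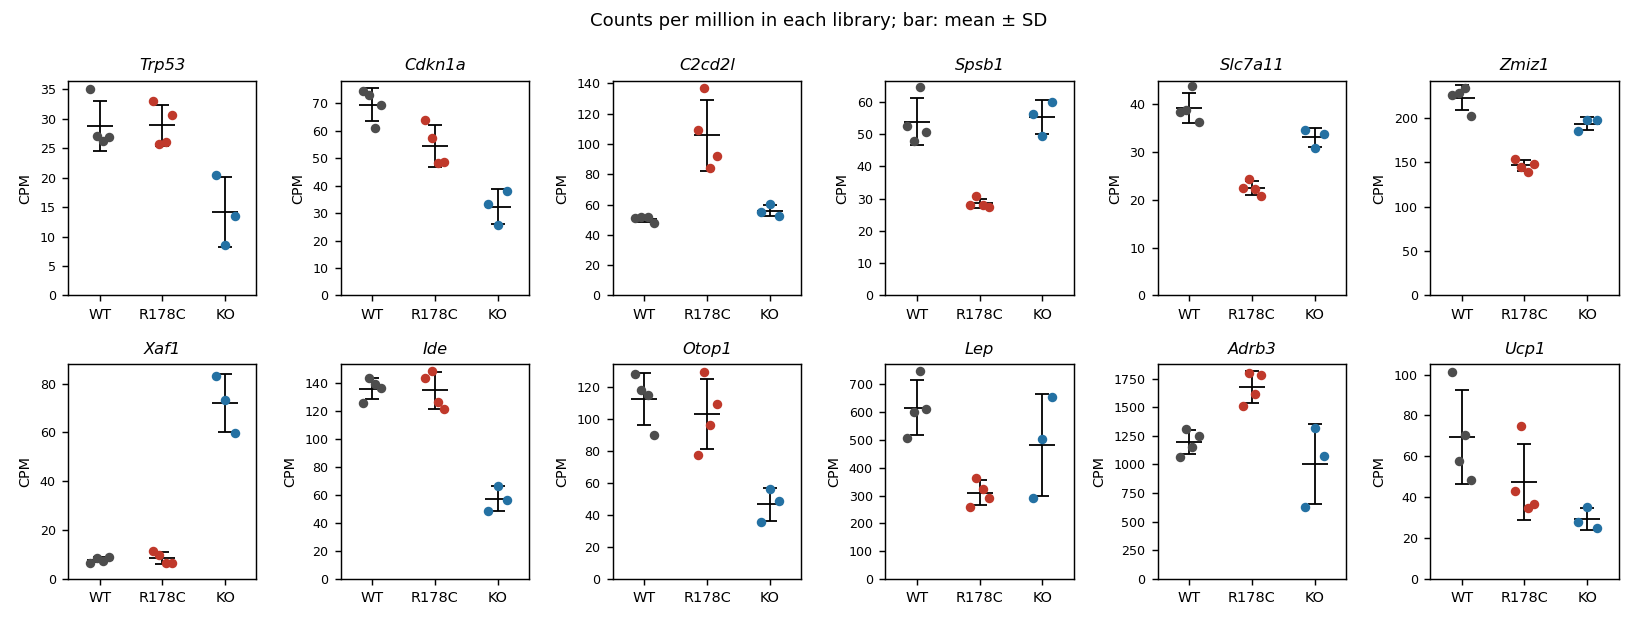
CPM of 12 genes in each library, grouped by genotype, with the group mean and SD (n = 4, 4 and 3). Cdkn1a, Ide and Otop1 were lowest and Xaf1 highest in the knockout, C2cd2l was highest and Spsb1, Slc7a11 and Zmiz1 were lowest in R178C, and Trp53 in the knockout was 20.4, 8.54 and 13.6 CPM.

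Gene lists were then compared between R178C and wild type with camera, and 12 of 26 were shifted. None of these calls held when the correlation between genes was estimated from the data. The oxidative phosphorylation list had positive log2 fold changes in 75 of 75 genes (median 0.20, adjusted p = 6.09e-10; adjusted p = 0.807 with an estimated correlation). None of its genes passed over the list alone, with Ndufa13 at 0.30 and Ndufs8 at 0.24 (edgeR adjusted p = 0.535 and 0.537). Fatty acid oxidation was shifted up with 22 of 30 genes positive (median 0.092, adjusted p = 0.0421; 0.807 with an estimated correlation), and 3 members rose when adjusted over the list alone. Its members Slc27a1, a fatty acid transporter, and Ehhadh, a peroxisomal enzyme, had log2 fold changes of 0.57 (adjusted p = 0.142) and 0.70 (0.272). Fatty acid and triglyceride synthesis (22 of 28 positive, median 0.14, adjusted p = 0.0309) and lipolysis and beta-adrenergic signalling (21 of 31, median 0.084, adjusted p = 0.0388) were shifted up too. Both had an adjusted p = 0.807 with an estimated correlation. Adjusted over the list alone, 0 and 1 of their members rose. Elovl5 (0.45), Dgat1 (0.35), the niacin receptor gene Hcar2 (0.72) and Pik3r1 (0.59) did not pass over all genes (edgeR adjusted p = 0.299, 0.331, 0.163 and 0.333). Adipocyte markers were higher in 15 of 19 genes (median 0.16, adjusted p = 0.0388; 0.807 with an estimated correlation). Lep was the 1 member that fell when adjusted over the list alone, and Cidec had a log2 fold change of 0.33 (edgeR adjusted p = 0.487).

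Single libraries carried several of these calls. Without R178C library 2 the adjusted p became 0.117 for fatty acid oxidation, 0.201 for synthesis, 0.0679 for lipolysis and 0.158 for adipocyte markers. Without wild-type library 1 it was 0.0655 for oxidation, 0.0887 for lipolysis and 0.163 for adipocyte markers, and without wild-type library 4 it was 0.123 for oxidation and 0.0727 for synthesis. Further calls ended without R178C library 3 (oxidation 0.0792, lipolysis 0.0558, adipocyte markers 0.0548), without wild-type library 3 (oxidation 0.0975) and without knockout library 3 (oxidation 0.0577, adipocyte markers 0.0521). The oxidative phosphorylation call held without each library in turn.

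The lists of p53 targets, interferon response, adipose inflammation and cell cycle went the other way, each without passing with an estimated correlation. The p53 target genes were shifted down in R178C, with 28 of 41 negative (median −0.14, adjusted p = 0.0143; adjusted p = 0.0987 with an estimated correlation, fry adjusted p = 0.0446). None passed when adjusted over the list alone, with Sesn2 at −0.50 (edgeR adjusted p = 0.299) and Eda2r at −1.66 (0.280). That call ended without wild-type library 1 (0.0827) or R178C library 2 (0.0515). Interferon response genes were negative in 22 of 26 (median −0.21, adjusted p = 0.000539; 0.807 with an estimated correlation). None passed over the list alone, with Cxcl10 at −0.85 (edgeR adjusted p = 0.356) and Gbp3 at −0.43 (0.494). Adipose inflammation genes were negative in 10 of 14 (median −0.23, adjusted p = 0.0388; 0.296 with an estimated correlation). Serpine1, the plasminogen activator inhibitor, was the 1 member that fell when adjusted over the list alone, from 23.6 ± 4.41 to 10.9 ± 2.04 CPM (log2 −1.12, adjusted p = 0.152 over all genes). Cell cycle genes were negative in 28 of 35 (median −0.23, adjusted p = 0.0388; 0.807 with an estimated correlation), with Ndc80 at −0.80 (0.790), and none passed alone or over the list alone. Without R178C library 2 the adjusted p was 0.0851 for inflammation and 0.218 for the cell cycle, without R178C library 3 it was 0.0558 for both, and without wild-type library 4 it was 0.205 and 0.0600. Inflammation also missed the threshold without knockout library 1 (0.0679) and the cell cycle without wild-type library 1 (0.0887).

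Markers of other cell types differed between R178C and wild type beside these lists. Erythrocyte genes were higher in 8 of 8 (median 0.83, adjusted p = 8.08e-16; 0.0987 with an estimated correlation, fry adjusted p = 0.00574). All 8 rose when adjusted over the list alone, with the beta-globin gene Hbb-bt at 110 ± 14.7 CPM in wild type and 197 ± 31.4 CPM in R178C (log2 0.84, adjusted p = 0.0592 over all genes). Hbb-bt and Hbb-b2 had nearly the same counts in every library (1461 and 1454 in wild-type library 1, 2226 and 2210 in R178C library 1). They are thus not separate measurements, and in each fit the counts of members of this list overstate the support. Skeletal muscle markers were lower in 18 of 18 (median −2.24, adjusted p = 1.48e-12; 0.296 with an estimated correlation). When adjusted over the list alone 13 fell, and myoglobin, Mb, was at 8.95 ± 0.687 and 5.56 ± 0.527 CPM (log2 −0.68, edgeR adjusted p = 0.181) and Myoz1 at −3.24 (0.280). T cell markers were lower in 17 of 17 (median −0.57, adjusted p = 0.0388; 0.807 with an estimated correlation), with Cd3g at −0.84 (0.865) and no member passing over the list alone. The T cell call ended without wild-type library 1 (0.246), R178C library 2 (0.201), 3 (0.0988) or 4 (0.0678), or knockout library 3 (0.0521). B cell markers were negative in 15 of 15 without passing (median −0.39, adjusted p = 0.201). The other 13 lists had an adjusted p of 0.0784 to 0.898. Among them were stromal cells (median 0.088, adjusted p = 0.0784), nerve (0.16, 0.129), endothelium (−0.089, 0.180), extracellular matrix (median −0.0079 but mean 0.11 and test upward, 0.187), skin (0.25, 0.180), circadian clock (0.099, 0.819), macrophages (−0.011, 0.819) and mammary epithelium (0.047, 0.819). Brown and beige adipocyte genes had a median of −0.097 and a mean of 0.15 with the test downward (0.657), and mitochondrial biogenesis a median of 0.038 and a mean of −0.0025 with the test upward (0.898).

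To ask what differed in tissue without p53, the 3 knockout libraries were compared with wild type, and 8 genes rose and 17 fell. The labels give the wild type as homozygous for the arginine allele and name no litter. A difference between mouse lines therefore cannot be told apart from loss of p53, here or in R178C against the knockout. Cdkn1a, the p53 target gene of the cell cycle inhibitor p21, fell from 69.5 ± 6.07 to 32.3 ± 6.29 CPM (log2 −1.11 ± 0.149, edgeR adjusted p = 0.0162; SD and SE, n = 4 and 3). Bbc3, the p53 target gene of the pro-apoptotic protein PUMA, rose from 29.8 ± 2.18 to 47.8 ± 2.58 CPM (0.68 ± 0.098, adjusted p = 0.0224). Xaf1, an interferon-inducible gene of apoptosis that lies on the same chromosome as Trp53, rose from 7.85 ± 1.08 to 72.2 ± 11.8 CPM (3.20 ± 0.204, adjusted p = 6.61e-05). Ide, the insulin-degrading enzyme gene, fell from 136 ± 7.77 to 57.0 ± 8.89 CPM (−1.25 ± 0.115, adjusted p = 0.00123). Nrip1, a corepressor of energy expenditure genes in fat, fell from 191 ± 32.7 to 88.3 ± 19.9 CPM (−1.12 ± 0.165, adjusted p = 0.0240). Otop1, a proton channel gene of brown and beige fat, fell from 112 ± 16.3 to 46.6 ± 10.3 CPM (−1.27 ± 0.201, adjusted p = 0.0370).

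Slc43a2, an amino acid transporter gene, rose from 74.6 ± 6.24 to 152 ± 18.7 CPM in the knockout (log2 1.02, edgeR adjusted p = 0.00123). Also rising were Ocel1 (1.28, adjusted p = 0.000350), the collagen gene Col14a1 (1.28, 0.00954), the calcium channel gene Cacna1a (1.33, 0.0162), Nxnl1 (1.51, 0.0224) and Zfp868 (1.23, 0.0224). The non-coding transcript 2610507I01Rik fell from 20.3 ± 1.34 to 1.92 ± 0.285 CPM (−3.39 ± 0.128, adjusted p = 5.54e-07). The glycosyltransferase gene B3gnt3 (−1.83, adjusted p = 0.00281), Rnf150 (−1.16, 0.00209) and the clone-named 4931408D14Rik (−1.45, 0.0240) fell as well. The inflammasome sensor gene Nlrp1a had 2, 0 and 1 counts and its relative Nlrp1c-ps 1, 0 and 0 counts in the knockout libraries, against 0.994 ± 0.258 and 0.718 ± 0.0938 CPM in wild type. As near-identical copies their values are uncertain. Mdm2 (−0.02, adjusted p = 0.941), Adrb3 (−0.25, 0.542), Pnpla2 (−0.20, 0.564), Lipe (−0.30, 0.444), Lep (−0.35, 0.463) and Adipoq (0.05, 0.923) did not pass. Ucp1, the uncoupling protein of thermogenic fat, had 69.4 ± 23.0 CPM in wild type and 29.4 ± 5.34 CPM in the knockout without passing (−1.24 ± 0.311, adjusted p = 0.183). Ppargc1a had a log2 fold change of −0.69 (adjusted p = 0.314).

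The number of called genes, 25, moved with single libraries. It was 104 (48 up, 56 down) without knockout library 1, with all 25 among them, 152 without knockout library 2 and 13 without knockout library 3. It was 13, 7, 14 and 8 without wild-type libraries 1, 2, 3 and 4, and 15 without R178C library 3 or 4. The fit of these 2 groups alone gave 6 genes, DESeq2 232 and voom with library weights 904.

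Of the 26 lists, 14 were shifted in the knockout against wild type (camera), none of them with an estimated correlation. Lipid and mitochondrial lists were shifted down: fatty acid oxidation (28 of 30 negative, median −0.32, adjusted p = 8.78e-10), fatty acid and triglyceride synthesis (25 of 28, −0.39, 1.03e-08) and mitochondrial biogenesis and the tricarboxylic acid cycle (28 of 31, −0.28, 2.52e-09). So were lipolysis and beta-adrenergic signalling (27 of 31, −0.27, 9.59e-06) and cholesterol synthesis (19 of 23, −0.26, 0.000249). For these 5 lists the adjusted p was 0.448 with an estimated correlation. Adjusted over the list alone, 8, 1, 3, 0 and 0 of their members fell, and over all genes none did. Cpt1b, the muscle and brown fat isoform of the mitochondrial fatty acid entry enzyme, had 78.0 ± 12.1 CPM in wild type and 38.8 ± 6.45 CPM in the knockout (edgeR log2 −1.01, adjusted p = 0.0636). Acsl1, Agpat2, Suclg1, Prkar2b and Dhcr24 had log2 fold changes of −0.54, −0.82, −0.44, −0.48 and −0.61 (adjusted p of 0.176 to 0.247). Brown and beige adipocyte genes were lower in 20 of 26 (median −0.45, adjusted p = 2.12e-07; 0.304 with an estimated correlation, fry adjusted p = 0.0341). In that list Otop1 fell, 10 members fell and 1 rose when adjusted over the list alone, and Plin5 (−0.94, adjusted p = 0.121) and the deiodinase gene Dio2 (−1.65, 0.183) did not pass over all genes. Oxidative phosphorylation was lower in 67 of 75 genes (median −0.15, adjusted p = 1.93e-06; 0.710 with an estimated correlation). Adipocyte markers were lower in 15 of 19 (−0.25, 0.000543; 0.624 with an estimated correlation). Neither list had a member passing over the list alone, with Cycs at −0.32 (edgeR adjusted p = 0.320) and Plin4 at −0.62 (0.323).

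Knockout library 1, which had the lowest adipocyte marker mean, carried part of these shifts. Without it the medians were −0.13 for fatty acid oxidation (adjusted p = 8.49e-05), −0.12 for synthesis (0.00273), −0.14 for mitochondrial biogenesis (3.10e-05) and −0.29 for brown and beige adipocyte genes (8.49e-05). With an estimated correlation these 4 lists did not pass in that fit either (adjusted p = 0.687, 0.687, 0.558 and 0.363). Its absence ended the calls of lipolysis (−0.05, 0.0836), cholesterol synthesis (−0.055, 0.0922), adipocyte markers (−0.03, 0.981) and oxidative phosphorylation, whose median became 0.07 (0.135).

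Macrophage markers were higher in 14 of 14 genes in the knockout (median 0.48, camera adjusted p = 2.25e-07; 0.254 with an estimated correlation, fry adjusted p = 0.0255). When adjusted over the list alone 5 rose, and the complement gene C1qa had 95.4 ± 12.2 CPM in wild type and 133 ± 15.8 CPM in the knockout (log2 0.48, edgeR adjusted p = 0.170). Without knockout library 1 the macrophage median was 0.32 (4.43e-05; 0.363 with an estimated correlation). Stromal cell markers were higher in 15 of 18 (median 0.31, adjusted p = 0.00439; 0.448 with an estimated correlation), with Col1a1 at 0.46 (edgeR adjusted p = 0.299) and Lum at 0.41 (0.308). The stromal call ended without knockout library 2 (0.142) or 3 (0.0907). Smooth muscle markers were lower in 9 of 11 (median −0.20, adjusted p = 0.00412; 0.448 with an estimated correlation). Over the list alone 1 fell, Myh11 was at −0.65 (edgeR adjusted p = 0.217) and Cnn1 at −1.0 (0.314). The smooth muscle list missed the threshold without knockout library 3 (0.0913).

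Cell cycle genes were higher in 35 of 35 in the knockout (median 0.88, camera adjusted p = 7.18e-07; 0.531 with an estimated correlation). No member passed over the list alone, with E2f1 at 0.55 (edgeR adjusted p = 0.175) and Tpx2 at 1.36 (0.301). The cell cycle median was 0.02 (0.981) without knockout library 1, which had the highest lymphocyte markers. Interferon response genes were higher in 20 of 26 (median 0.22, adjusted p = 0.00570; 0.701 with an estimated correlation), of which Xaf1 rose and Oas1a was at 0.89 (edgeR adjusted p = 0.228). The interferon median was −0.08 (0.802) without knockout library 1, and the adjusted p was 0.0715 without wild-type library 1. Immediate early and stress genes were higher in 17 of 24 (median 0.33, adjusted p = 0.0495; 0.448 with an estimated correlation), with Junb at 1.07 (0.206) and none passing over the list alone. Their call ended without any one of the knockout libraries (0.0836, 0.123 and 0.0907), wild-type library 2 (0.282) or R178C libraries 2 (0.0552), 3 (0.0570) and 4 (0.0604).

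The p53 target genes as a list were not shifted in the knockout, with 21 of 41 positive (median 0.013 and mean 0.012 with the test downward, camera adjusted p = 0.316). The fit without knockout library 1 had 15 of 41 positive (median −0.10, adjusted p = 0.0902; 0.539 with an estimated correlation). In the fit of all libraries 2 rose and 3 fell when adjusted over the list alone. There Bbc3 and Cdkn1a also passed over all genes, and Sesn2 (−0.72, edgeR adjusted p = 0.144) and Trim47 (0.37, 0.205) did not. T cell markers were positive in 17 of 17 (median 1.85, adjusted p = 0.163) and B cell markers in 15 of 15 (median 0.89 and mean 0.85, with the test downward, 0.316). Without knockout library 1 the T cell median was −0.18 (0.0226), the B cell median −0.96 (3.22e-05) and the skeletal muscle median −0.72 (0.00102). With an estimated correlation the adjusted p of these 3 lists in that fit was 0.747, 0.687 and 0.687. The other 12 lists, the p53, T cell and B cell lists included, had an adjusted p of 0.160 to 0.903. Test and median were of opposite sign for skeletal muscle (median 0.34) and skin (0.018) and test and mean for the circadian clock (mean 0.038). Without knockout library 1 the extracellular matrix list (median 0.066, 0.0125; 0.687 with an estimated correlation) and the endothelial list (0.29, 0.0226; 0.716) passed as well at the preset correlation.

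The direct comparison of R178C with the knockout asked whether the mutant tissue differed from tissue without p53, and 35 genes were higher and 18 lower in R178C. Xaf1 had 8.50 ± 2.34 CPM in R178C and 72.2 ± 11.8 CPM in the knockout (log2 −3.07, edgeR adjusted p = 9.77e-05; SD, n = 4 and 3). Others that had also differed between the knockout and wild type were Ide (135 ± 13.1 and 57.0 ± 8.89 CPM, 1.24, adjusted p = 0.00125), Otop1 (1.14, 0.0444) and Bbc3 (−0.62, 0.0257). Spsb1, lower in R178C than in wild type, was also lower than in the knockout (28.6 ± 1.48 and 55.3 ± 5.30 CPM, −0.95, 0.00738), as was Ptpre (−0.91, 0.0135). Hcar2 had 96.0 ± 6.56 CPM in R178C against 48.1 ± 13.2 CPM in the knockout (0.996, adjusted p = 0.0427). The acylcarnitine carrier gene Slc25a20 had 118 ± 4.91 against 75.8 ± 9.82 CPM (0.64, adjusted p = 0.0232), and Clstn3, a calsyntenin gene, had 150 ± 42.7 against 62.4 ± 12.9 CPM (1.26, 0.0427). The potassium channel gene Kcnj15 (1.56, adjusted p = 0.0145), Zyg11a (1.73, 0.0245), B3gnt3 (1.85, 0.00298) and Fgfbp3 (1.39, 0.0359) were higher. Mef2b (−2.57, adjusted p = 0.0156), Slc43a2 (−1.27, 0.000252), Zfp868 (−1.41, 0.0135), Cdk5r1 (−1.20, 0.0296), Cacna1a (−1.16), Ocel1 (−1.16) and Col14a1 (−1.13) were lower in R178C. Clone-named genes added 3 that were higher, 2610507I01Rik among them (3.58, adjusted p = 3.35e-07), beside Nlrp1c-ps with 1, 0 and 0 counts in the knockout. Cdkn1a had a log2 fold change of 0.76 (adjusted p = 0.0624), Adrb3 one of 0.74 (0.138), Pnpla2 0.50 (0.179), and Lipe 0.46 (0.213). Ucp1 had one of 0.69 (adjusted p = 0.222), Ppargc1a 0.23 (0.583), Lep −0.64 (0.186), Adipoq 0.22 (0.549), Mdm2 −0.13 (0.534) and Trp53 1.03 (0.107), and none of these passed.

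The count of 53 became 201 without knockout library 1, with all 53 among them, 2498 without knockout library 2 and 9 without knockout library 3. It was 33, 35, 36 and 30 without wild-type libraries 1 to 4, and 27, 13, 15 and 19 without R178C libraries 1 to 4. The fit of these 2 groups alone gave 7 genes, DESeq2 665 and voom with library weights 1149.

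In R178C against the knockout 17 lists were shifted (camera), none of them with an estimated correlation. Higher in R178C were oxidative phosphorylation (74 of 75 positive, median 0.34, adjusted p = 1.80e-16), fatty acid oxidation (28 of 30, 0.43, 1.25e-11), fatty acid and triglyceride synthesis (27 of 28, 0.54, 2.28e-11), and lipolysis and beta-adrenergic signalling (27 of 31, 0.35, 6.05e-08). So were mitochondrial biogenesis (28 of 31, 0.33, 7.12e-08), brown and beige adipocyte genes (20 of 26, 0.42, 4.82e-06) and adipocyte markers (17 of 19, 0.41, 8.55e-06). With an estimated correlation their adjusted p was 0.387 for oxidative phosphorylation and adipocyte markers, 0.314 for brown and beige genes and 0.356 for the other four. Of these lists only brown and beige genes passed with fry (adjusted p = 0.0444). Adjusted over the list alone 17 members of fatty acid oxidation, 14 of synthesis, 6 of lipolysis, 5 of mitochondrial biogenesis, 9 of the brown and beige list, 1 adipocyte marker and 0 of oxidative phosphorylation were higher. Over all genes Slc25a20, Hcar2 and Otop1 were. Ehhadh (1.06, edgeR adjusted p = 0.0588), Slc27a1 (0.61, 0.0588), Acsl1 (0.62, 0.0746), Dgat1 (0.52, 0.0923), Gpam (0.70, 0.0968), the adenylyl cyclase gene Adcy5 (0.90, 0.0624) and Cox8b (0.98, 0.0624) did not pass over all genes. These 7 lists passed without each library in turn, knockout library 1 with its low adipocyte mean included (medians without it 0.22 for fatty acid oxidation, 0.29 for synthesis, 0.14 for oxidative phosphorylation, 0.14 for lipolysis, 0.17 for mitochondrial biogenesis, 0.27 for brown and beige genes and 0.16 for adipocyte markers). With an estimated correlation their adjusted p without it was 0.402 to 0.535.

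Erythrocyte genes were higher in R178C than in the knockout in 8 of 8 (median 0.94, camera adjusted p = 2.75e-10; 0.276 with an estimated correlation, fry adjusted p = 0.00582), each of them also when adjusted over the list alone. Of these, 4 passed over all genes, among them Hbb-bt (197 ± 31.4 against 98.1 ± 7.04 CPM, edgeR adjusted p = 0.0156), Hbb-bs (0.94, 0.0241) and Alas2, the heme synthesis gene of red cells (18.7 ± 2.70 against 9.79 ± 1.31 CPM, 0.0260). The globin genes are near-identical copies, so their values are uncertain, and Hbb-bt and Hbb-b2 do not count as separate measurements. Macrophage markers were lower in 13 of 14 (median −0.48, adjusted p = 1.62e-06; 0.276 with an estimated correlation, fry adjusted p = 0.00963), 10 of them when adjusted over the list alone, with C1qc at −0.51 (edgeR adjusted p = 0.117). Interferon genes were lower in 26 of 26 (median −0.37, adjusted p = 2.30e-07; 0.356 with an estimated correlation), 3 of them over the list alone and Xaf1 over all genes, with a median of −0.22 (0.00139; 0.535 with an estimated correlation) without knockout library 1. Cell cycle genes were lower in 35 of 35 (median −1.11, 2.55e-09; 0.387 with an estimated correlation), with Aurkb at −1.52 (edgeR adjusted p = 0.128) and a median of −0.26 (0.00704; 0.535 with an estimated correlation) without knockout library 1. Skeletal muscle markers were lower in 17 of 18 (median −2.87, 3.03e-06; 0.356 with an estimated correlation), 16 over the list alone, with Myoz1 at −3.70 (0.103). The knockout libraries differed, with muscle means of 3.29, −0.082 and 2.09 log2 CPM against −0.028 to 0.46 in R178C, so that knockout library 2 was below all 4 R178C libraries. The median was −1.75 without knockout library 1 (0.00126; 0.535 with an estimated correlation), with no member passing over the list alone.

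Adipose inflammation (13 of 14 negative, median −0.57, camera adjusted p = 0.0261; 0.314 with an estimated correlation) missed the threshold without knockout library 3 (0.176), with no member passing over the list alone. Immediate early genes (17 of 24 negative, −0.42, 0.0191; 0.356 with an estimated correlation) missed it without knockout library 2 (0.0542) and had a median of −0.26 (0.0188; 0.535) without knockout library 1. Over the list alone 1 of them was higher and 8 lower, with Junb at −1.29 (edgeR adjusted p = 0.0898). T cell markers were lower in 17 of 17 (median −2.42, 0.00362; 0.565 with an estimated correlation), all of them over the list alone, with Cd3e at −2.51 (0.173), and the median was −0.39 (0.822) without knockout library 1. Cholesterol synthesis (median 0.17, 0.0412; 0.565 with an estimated correlation) and nerve markers (12 of 14 positive, 0.36, 0.0413; 0.450 with an estimated correlation) missed the threshold without that library too (−0.10, 0.894 and 0.13, 0.433). Cholesterol synthesis also missed it without R178C library 2 (0.247), and nerve markers without R178C library 1 (0.0581) or 4 (0.0813) or knockout library 3 (0.116). The other 9 lists had an adjusted p of 0.0829 to 0.946. Test and median were of opposite sign for B cells (median −1.20) and the circadian clock (−0.053) and test and mean for extracellular matrix (mean −0.010) and skin (−0.16).

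**Figure D3:**
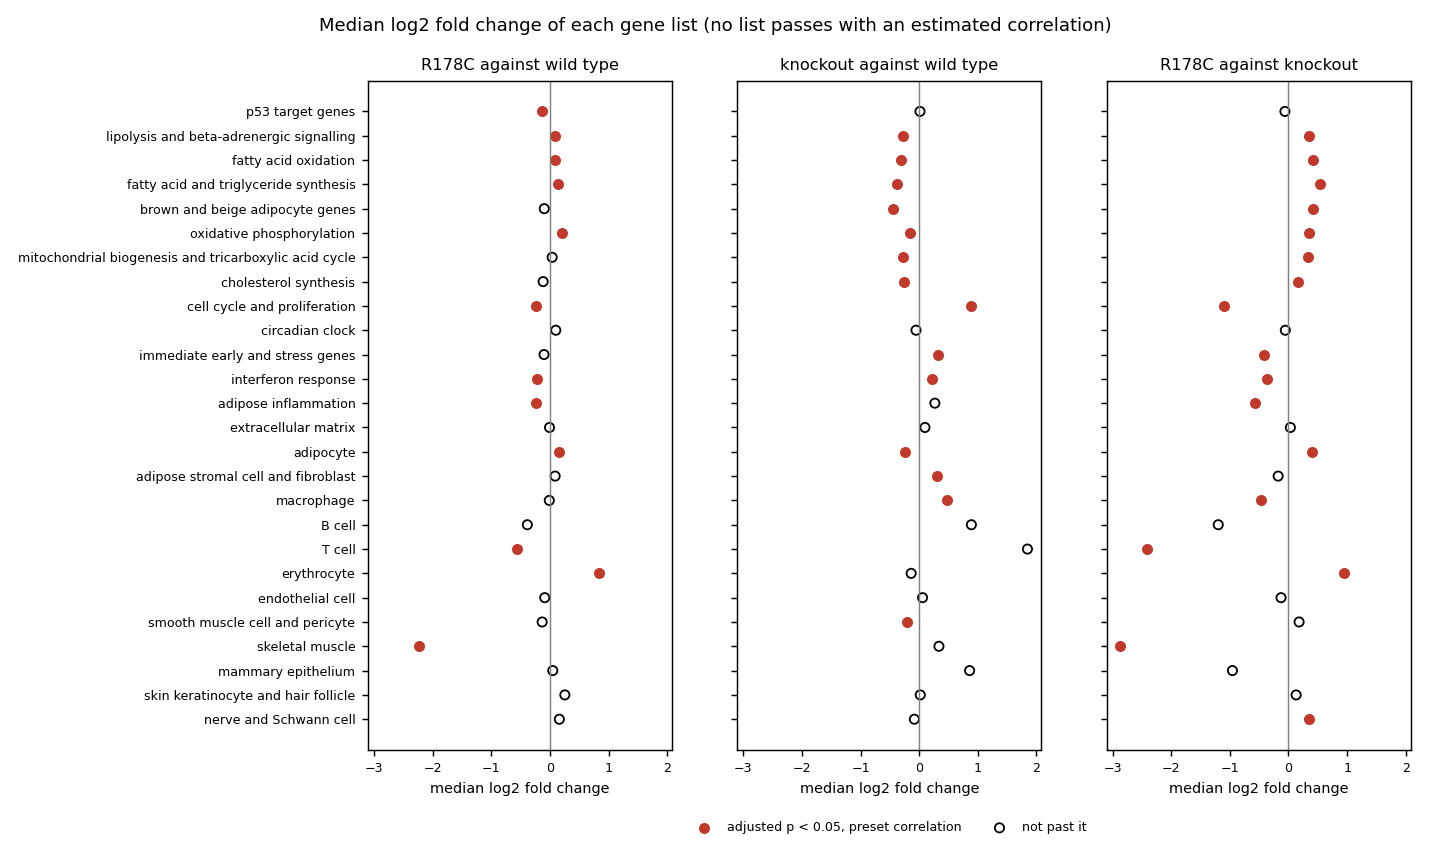
Median log2 fold change of the 26 gene lists in the 3 comparisons, with filled points for lists past the camera threshold at the preset correlation (12, 14 and 17 lists). Oxidative phosphorylation had a median of 0.20 in R178C and −0.15 in the knockout against wild type and 0.34 between them, and skeletal muscle markers had −2.24 in R178C against wild type.

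The genes called against wild type were set side by side to ask whether R178C and loss of p53 changed the same genes, and no gene was called in both (0 up, 0 down, by edgeR). DESeq2 gave 11 genes in both, voom with library weights 82, and at an unadjusted p under the threshold there were 1300 genes in R178C and 1946 in the knockout. Independent lists of the sizes of the edgeR calls (2 and 8 up, 6 and 17 down) would share 0.0011 genes upward and 0.0072 downward. Unchanged groups, simulated together with 4 controls shared by both comparisons, had 0 to 2 calls, too few to share any, and give no reference for the shared genes. Across genes, which are not independent replicates, the log2 fold changes had a correlation of −0.0573 and a covariance of −0.00731. Unchanged simulated groups that share 4 simulated controls had 0.458 and 0.0405. All simulated libraries, the controls included, were drawn with the spread of the fit of all libraries. Knockout library 1 widened that spread (square root of the common dispersion 0.223 with it and 0.125 without), so these simulated values are no neutral reference. With 2 wild-type libraries as the control of each comparison the correlation was −0.322 to 0.0654 over 6 splits. Without knockout library 1, 6 genes were called up and 7 down in both (0.645 and 0.914 for independent lists, which takes no account of the shared controls), and the covariance was 0.0377 against a simulated 0.0232. With the controls split, that fit gave 0 shared genes upward and 0 to 1 downward, a correlation of 0.0313 to 0.239 and a mean covariance of 0.0157. D430019H16Rik, chosen after its values were seen, was 1 of the 7, with 44.6 ± 7.95 CPM in wild type, 14.7 ± 2.65 in R178C and 14.3 ± 8.49 in the knockout.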

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

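Of the tests in this part, those of T cell expansion, of muscle means within pairs, of muscle expression in R178C fat itself and of the muscle genes that fat hardly expresses were chosen only after the result was seen. In a group of 4 libraries, a library was picked out when its gap to the nearest other one was a larger part of the range of the group than Dixon's published critical value, which chance gives in about 1 of 20 groups, and 11 of 140 tests did so. Wild-type library 1 was highest for Trp53 (35.1 CPM against 26.2 to 27.1, gap 0.896 of the range), Rnf150 (74.6 against 66.5 to 67.6 CPM, 0.867), B cell markers (5.41 against 3.98 to 4.11 log2 CPM, 0.905) and T cell markers (3.90 against 2.71 to 2.88, 0.857). Wild-type library 2 was lowest for immediate early genes (3.43 against 3.81 to 3.85, 0.899) and wild-type library 4 highest for macrophage markers (5.21 against 5.17 to 5.18, 0.843). R178C library 2 was highest for Kcnj15 (60.5 against 45.6 to 46.4 CPM, 0.948) and adipocyte markers (10.9 against 10.8 log2 CPM, 0.919). R178C library 4 was lowest for stromal markers (5.80 against 5.98 to 6.02, 0.841) and highest for skeletal muscle markers (0.46 against −0.028 to 0.050, 0.841), and R178C library 1 was highest for skin markers (2.02 against 1.70 to 1.73, 0.8996).

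Lymphocyte markers were far higher in knockout library 1 (B cell mean 6.64, T cell mean 6.31 log2 CPM) than in the other 10 libraries. Lymph node tissue dissected with the fat, as the inguinal pad holds a lymph node, may be a source: genes of lymph node vessels and stroma (7 of 8 had values, with Glycam1 at 5.96 and Ccl21a at 5.55 log2 CPM) were 2.66 below the B cell mean (−2.66), within the −2.90 to −2.09 of the 8 wild-type and R178C libraries. An expansion of T cells, which loss of p53 is known to allow, stays open too, because the T cell mean minus the B cell mean was −0.326, above the −1.90 to −1.09 of those 8 libraries. Knockout libraries 2 and 3, at 0.630 and −0.645, were also above them, and their stroma differences were −0.243 and −1.96. Knockout library 1 had a cell cycle mean of 3.35. Wild-type library 1 and R178C library 1, with B cell means of 5.41 and 5.09, each had a cell cycle mean of 1.82. What this means for either source was not tested. Expansion of T cells alone would raise neither the B cell mean, which was 1.23 above the next library (SD of the 8 wild-type and R178C libraries 0.838), nor the vessel and stroma mean (3.98, next 2.53), which argues against it as the only source, and both can hold together.

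Skeletal muscle markers were lower in R178C than in wild type in 18 of 18 genes (median −2.24). For the difference of list means the exact permutation test, two-sided, gave p = 0.0286, and within the 4 pairs of the same number p = 0.125. Each is the smallest p that these group sizes allow. The list was picked for its shift in the same data, so neither p is independent support. Muscle carried over in dissection and lower muscle gene expression in R178C fat itself cannot be told apart with these tables. The first test of carry-over asked for a shift below −0.5 in further muscle genes, and 11 of 30 that passed the filter had a median of −0.109, but those genes had a median of 38 counts in the knockout library with the fewest counts of the muscle gene Ckm, a baseline in fat that hides a change of muscle content, so the bound was wrong. Over the 19 further genes with at most 5 counts there, the summed level was 7.51 ± 5.10 CPM in wild type and 2.63 ± 0.553 CPM in R178C, a log2 ratio of −1.51. Fixed and further muscle genes moved together over 11 libraries (Pearson r = 0.938, permutation p = 6.0e-05; Spearman rho = 0.909, permutation p = 0.00026; r = 0.850 without the 2 farthest), and the list mean ranged by 1.61 within wild type, 0.489 within R178C and 3.38 within the knockout, which leaves both open.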

How the results depend on the processing

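The longest transcript per gene, the unmatched transcripts kept and the first library of each group left out were chosen only after the data were seen. The counts of genes and lists past the threshold, the genes in both comparisons and the Trp53 level in the knockout stayed on their side of the threshold, or within 1.5 times, in 117 of their values under alternatives, and became weaker in 38 and stronger in 32. Only the Trp53 level could change direction, as counts have none, and it did so in 0 of its values. For named genes 1394 values stayed, 221 became weaker, 46 became stronger and 32 changed direction. For gene lists these numbers were 1571, 167, 40 and 68. The longest transcript per gene (8, 25 and 53 genes in the order R178C against wild type, knockout against wild type, R178C against knockout), the unmatched transcripts kept (8, 24 and 54) and DESeq2's size factors (8, 32 and 52) stayed within 1.5 times. Unless a fit used fewer libraries or genes, the cause of a difference was not tested. Pseudocount alternatives apply only to normalized values and were not run on counts, and DESeq2 gives no list test.

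Leaving out each library in turn gave 0 to 423, 7 to 152 and 9 to 2498 genes in that order, with the highest values without knockout library 1 (423), knockout library 2 (152) and knockout library 2 (2498). Wild-type library 2 or R178C library 4 left out gave the 0, wild-type library 2 the 7 and knockout library 3 the 9. Lists called in R178C against wild type ran from 5 (without R178C library 2) to 14, with 6 without wild-type library 1 or R178C library 3 and 8 without wild-type library 4. Genes in both comparisons ran from 0 to 13, the 13 without knockout library 1. The Trp53 log2 fold change in the knockout ran from −1.40 to −0.76. With only the 2 groups compared in the fit, the counts were 389, 6 and 7, and Trp53 in R178C turned to −0.00054. Without the first library of each group they were 198, 60 and 201, with 4 genes in both and Trp53 at −1.29 in the knockout (adjusted p = 0.0125).

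DESeq2's Wald test gave 143, 232 and 665 genes, 11 in both, a Trp53 level of −1.02 in the knockout (adjusted p = 0.00856) and −0.0028 for Trp53, R178C against wild type. Voom with library weights, which gave knockout library 1 a weight of 0.0765, called 552, 904 and 1149 genes, 82 in both and 8 lists in the knockout, with Trp53 at −1.13 (adjusted p = 0.00296). The B cell markers as a covariate gave 122, 2701 and 3140 genes, 40 in both and Trp53 at −0.98 (adjusted p = 0.000105). With the mammary markers as a covariate the counts were 168, 15 and 20 and Trp53 was at −1.51 (adjusted p = 0.0364). In the knockout against wild type that covariate ended the camera calls of fatty acid and triglyceride synthesis (adjusted p = 0.545), lipolysis (0.968) and cholesterol synthesis (0.825). Over all alternatives the adjusted p of Trp53 in the knockout ran from 0.000105 to 0.553. Camera with an estimated correlation called 0, 0 and 0 lists, against 12, 14 and 17 at the preset correlation and 2, 2 and 3 by fry.

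Directions that turned were mostly of values near 0. These were Trp53, R178C against wild type, with the mammary covariate (−0.042), a mean count of at least 50 (−0.00061) and DESeq2's size factors (−0.0034), and in the same comparison mitochondrial biogenesis with the B cell covariate (0.0050), mammary epithelium with the mammary covariate (0.021), and, without the first libraries, brown and beige genes (−0.032) and smooth muscle (−0.024). For lists the direction is that of the test, which can differ from the median given here. In the knockout against wild type voom turned the circadian clock (0.067), interferon response (−0.036) and skin (0.13), and the B cell covariate turned Mdm2 (0.012), Adipoq (−0.056), extracellular matrix (−0.023) and endothelium (−0.066). There the mammary covariate turned Adrb3 (0.13), Pnpla2 (0.064), oxidative phosphorylation (0.18), cell cycle (−0.16), circadian clock (0.00069), adipocyte (0.054), T cell (−0.81), erythrocyte (0.080), mammary epithelium (−0.30), skin (0.31) and nerve (0.034). The first libraries left out turned oxidative phosphorylation (0.029), circadian clock (0.0099), interferon response (−0.070), T cell (0.18) and skin (0.12). A mean count of at least 50 turned adipose inflammation (0.32), as did no filter (−0.16), which also turned endothelium (0.051) and skin (0.11). In R178C against the knockout voom turned Adipoq (−0.024), cholesterol synthesis (−0.17) and extracellular matrix (−0.047), and the mammary covariate turned Mdm2 (0.079), Ppargc1a (−0.064), Adipoq (−0.11), cholesterol synthesis (−0.11), extracellular matrix (−0.11) and T cell (−0.022). The first libraries left out turned Mdm2 (0.031), Ppargc1a (−0.040), Adipoq (−0.059), cholesterol synthesis (−0.086) and extracellular matrix (−0.069).

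Some directions turned when a single library was left out. In R178C against wild type the ranges were −0.069 to 0.11 for Trp53, −0.12 to −0.033 for brown and beige genes, 0.014 to 0.051 for mitochondrial biogenesis, 0.070 to 0.14 for the circadian clock, −0.067 to 0.015 for macrophage and −0.18 to −0.025 for smooth muscle. In the knockout against wild type they were −0.16 to 0.081 for Mdm2, −0.50 to 0.0010 for Adrb3, −0.11 to 0.30 for Adipoq, −0.30 to 0.069 for oxidative phosphorylation, 0.024 to 1.20 for the cell cycle, −0.14 to −0.021 for the circadian clock, −0.013 to 0.44 for inflammation and −0.073 to 0.15 for extracellular matrix. For cell types there they were −0.96 to 1.47 for B cell, −0.18 to 2.41 for T cell, −0.20 to −0.041 for erythrocyte, −0.22 to 0.29 for endothelium, −0.72 to 0.78 for skeletal muscle, −0.16 to 0.18 for skin and −0.50 to 0.13 for nerve. In R178C against the knockout they were −0.23 to 0.0043 for Mdm2, −0.075 to 0.47 for Ppargc1a, −0.049 to 0.38 for Adipoq, −0.10 to 0.31 for cholesterol synthesis, −0.20 to 0.070 for the circadian clock, −0.11 to 0.15 for extracellular matrix, −1.78 to 0.60 for B cell, −0.36 to 0.17 for endothelium and, for the list T cell, R178C against knockout, −3.03 to −0.39.

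With the replicate number as a block the counts were 14, 24 and 90 genes, of which 6, 18 and 43 were among those called without it. In R178C against wild type the block changed the calls of St3gal4 and Ptpre, and of no other named gene and no list. The numbers were not taken to pair the knockout libraries, with a correlation of 0.0907 for library 3 with wild type and 0.0239 with R178C. Of all 11 libraries, 6 correlated best with their own number, a hint from the data and not from the design.

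Other splits of the same libraries into groups of the same sizes were fitted, 35 for each comparison. For R178C against wild type the real split gave 8 genes and the highest other 0, and with only these groups in the fit 389 and 0, so that only the real one, 1 of the 35 splits, gave as many, the smallest share these group sizes allow. The same held for the knockout against wild type, with 25 genes and 0 (1 of the 35 splits). Of the 8 splits that part all 4 pairs of the same number, the other ones of R178C against wild type gave 0 genes in either fit and 0 to 9 lists with all libraries in the fit, while the split with 15 lists kept pairs together. With the numbers taken as pairs the real split is 1 of only 8. So few splits cannot exclude chance for the 8 or the 389 genes. For R178C against the knockout 2 of the 35 splits gave as many as the real 53, so chance was not excluded. The other one, with 852 genes, set knockout library 2 beside R178C libraries 2, 3 and 4, which points to a structure of the samples. It parted the libraries by lymphocyte markers. Those set together had B cell means of 0.19 to 4.15 log2 CPM, against 4.49 to 6.64 in the rest. Their T cell means were 0.82 to 2.25, against 3.56 to 6.31. Chance was not excluded for the numbers of lists: 12 lists in R178C against wild type (5 of the 35 splits, highest other 15), 14 in the knockout (18, highest other 17) and 17 between them (7, highest other 19). In the simulation, with these library sizes, spread and group sizes, few small changes were called. Of the 66 genes given a log2 fold change of 0.5, the share called was 12.1%, 9.09% and 15.2% in the 3 comparisons. That share need not hold for genes with few counts. The square root of the common dispersion was 0.223 with knockout library 1 and 0.125 without it.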

Other observations

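Genes in this part, and the fits given for them, were chosen after their values were seen. Of the tests the count of called neighbours was chosen only after the result was seen. With wild type and R178C alone in the fit, 389 genes passed, of which 4 are given here. The brown and beige list (camera adjusted p = 0.603) and the extracellular matrix list (0.360) were not called in that fit. Prdm16, a regulator of the brown and beige fat programme, fell from 51.6 ± 5.51 to 34.8 ± 2.12 CPM (SD, n = 4 each; log2 −0.57 ± 0.0833, edgeR adjusted p = 0.00943, against 0.539 with all 3 groups). Cited1, a marker of beige fat, rose from 0.280 ± 0.0668 to 6.44 ± 4.84 CPM with 34 to 187 counts in R178C against 3 to 5 in wild type (adjusted p = 0.00609, against 0.147), but knockout library 1 also had 73 counts. The matrix gene Postn, periostin, rose from 46.3 ± 2.0 to 140 ± 82.9 CPM (1.61, adjusted p = 0.0263, against 0.152), and Hsd11b2, which inactivates glucocorticoids, from 2.44 ± 0.514 to 6.29 ± 2.82 CPM (1.37, adjusted p = 0.0352, against 0.147).

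Some genes were low in both p53 genotypes. Trp53cor1, the p53-induced non-coding RNA lincRNA-p21, had 1.13 ± 0.148 CPM in wild type, 0.313 ± 0.127 in R178C and 0.233 ± 0.0960 in the knockout. It fell in R178C in the fit of those 2 groups (log2 −1.85, edgeR adjusted p = 0.0209, against 0.145 with all libraries) and in the knockout without knockout library 1 (−2.55, adjusted p = 0.0429, against 0.0601). D430019H16Rik fell in both without that library (−1.61, adjusted p = 0.00134, and −1.22, adjusted p = 0.0130, against 0.167 and 0.175 with all libraries). Without knockout library 1 the Wnt-binding stromal genes Sfrp2 (1.22, edgeR adjusted p = 0.0130, against 0.314) and Sfrp4 (1.41, 0.0421, against 0.338) and the lipid-associated macrophage gene Trem2 (1.49, 0.0421, against 0.183) rose in the knockout. That fit held only 2 knockout libraries. Trem2 had few counts, 12 to 27 in wild type and 28, 43 and 52 in knockout libraries 1, 2 and 3.

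Several of the 25 genes called in the knockout lay next to each other in gene order (assembly GRCm38.p6), with 4 having another called gene among their 10 nearest tested genes, Nlrp1a with Nlrp1c-ps and Ide with 4931408D14Rik, where 10000 random draws had a median of 0 and 1.55% had as many. That count was prompted by the pairs themselves. Of all 104 genes called without knockout library 1, the 25 among them, 20 had such a neighbour (0.18% of draws). Of the 79 that remain without the 25, 10 had one (5.37% of draws), so loss of p53 acting on scattered target genes stays open. Nlrp1a, Nlrp1c-ps and Xaf1 lay 70 to 80 tested genes from Trp53 and 2610507I01Rik, Slc43a2 and Abhd15 117, 129 and 157, 6 of the 25 on its chromosome, and passenger DNA, flanking sequence of another strain kept beside a targeted gene, may account for those. Among these genes Nlrp1a, at few counts, was also low in R178C, with 5, 4, 4 and 3 counts against 19, 18, 11 and 10 in wild type. That was not so for Nlrp1c-ps (7 to 11 against 7 to 12 counts), Xaf1 (6.43 to 11.2 against 6.62 to 8.87 CPM) or 2610507I01Rik (21.8 to 25.1 against 18.5 to 21.7 CPM). Leaving out called genes and knockout library 1, 45 of 197 genes near Trp53 (22.8%) had an unadjusted p under the threshold against 2126 of 13904 elsewhere (15.3%; odds ratio 1.64, Fisher's exact test, which takes neighbouring genes as independent, p = 0.00521). In R178C against wild type it was 35 of 191 against 2741 of 13497 (odds ratio 0.880, Fisher's exact test, p = 0.586), so passenger DNA stays open, as do local effects of p53 itself. Passenger DNA around Trp53 does not cover called genes on other chromosomes, such as Ide and its neighbour. Others there also lay near each other, though outside the 10 nearest tested genes. B3gnt3 lay 8 tested genes from Nxnl1, Ocel1 14 from Nxnl1 and Zfp868 63 from Ocel1. Cacna1a lay 28 from Rnf150 and Col14a1 8 from Fam83a. For none of these was an explanation tested.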
